A study of Mus musculus with 12 samples.

How the data were processed

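Circular RNAs (circRNAs) are closed RNA loops made when the end of an exon is spliced back to the start of the same or an earlier exon, and they are measured from reads that cross this back-splice junction. They were measured in liver RNA of 12 mice, whose strain the labels give as C57BL/8. Per the labels' protocols, every mouse was injected with carbon tetrachloride (CCl4), a liver toxin used to produce fibrosis in rodents, as a 10% preparation at 10 µl per 10 g of body weight, and livers were taken in week 8. The 6 Control mice had CCl4 alone. The 6 PZH mice were also given Pien Tze Huang (PZH), a traditional Chinese medicine, at 25 mg/ml each day from week 2 to week 8. Livers without CCl4 were not analysed here, so the values compare CCl4 plus PZH with CCl4 and not with healthy liver. The labels describe the samples as livers of separate mice, and each library was treated as 1 replicate.

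The deposited values are a signal in SRPBM, named so by the authors' table and used in this field for spliced reads scaled to the mapped reads of a library. Per the labels' protocols, RNA was extracted with Trizol and libraries followed a TruSeq RNA kit. Per the submitters' processing notes, Trim Galore (read trimming) and STAR (alignment) were used with the mouse assembly GRCm38, also called mm10. The versions of these programs, the circRNA caller, its filters and the exact SRPBM formula are not given in the sources used here. Low values of each library lay at or just above whole multiples of a step that puts its smallest value at 2 steps, as would be seen if 1 step were 1 read pair and junctions with 1 pair were listed at 0. Among values up to 8.5 steps, 56.8% to 63.8% per library lay between 0.05 below and 0.1 above a whole step. As the other values lay off whole steps, whole reads could not be recovered for the table, and no count model was used. A value divided by its library's step is called a read-pair equivalent below.

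Depth is known only through the table. The libraries held 80442 to 130487 read-pair equivalents on back-splice junctions, summing to 28922 to 41080 SRPBM. For circRNAs above 0 in at least 6 libraries with a median of 2 to 5 read-pair equivalents where above 0, 41.4% of entries were listed at 0. Negative binomial sampling around the mean of the entries above 0 would give 8.10%. Leaving the zeros out of that mean makes the expected share too low for such low circRNAs. Entries at 0 were also found for abundant circRNAs, so a 0 was read as "listed at 0" and not as absence. For circRNAs with any such entry the text gives library values, ranges or the number of libraries above 0, and no mean ± SD.

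The table gives each circRNA by chromosome, start and end only. Host genes were assigned here from the GENCODE M21 annotation of the same assembly: 15737 of 16445 circRNAs (95.7%) had both ends on exon boundaries of 1 gene, 628 had 1 end on a boundary, and 80 lay inside a gene without a matching boundary. For 144 circRNAs more than 1 gene was a possible host. This departs from the plan, under which host gene results were to be left out if the table named no hosts. Strand was taken from the host, and exon numbers refer to 1 matching transcript of it.

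The main test was limma 3.58.1 in R 4.3.3 with a variance trend on log2(SRPBM + 0.636), where the pseudocount is the median of the libraries' smallest values. CircRNAs above 0 in at least 6 of 12 libraries were tested, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(SRPBM + pseudocount) scale, which understates changes of low circRNAs. SRPBM summed over a host gene's circRNAs were tested in the same way. A set of 16 host gene lists with at least 5 tested circRNAs each was tested with camera (inter-gene correlation 0.01), with fry, run without the variance trend, beside it. Camera compares a list with all other circRNAs. Values with 1 number per library were compared with exact permutation tests over all 924 assignments of 6 of 12 libraries, in scipy 1.17.1. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

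The groups, tests, lists, most alternative settings and the rule for named circRNAs were fixed before the data were examined. That rule took the 10 circRNAs with the largest fold change past the threshold in each direction, filled up to 10 by the smallest unadjusted p and then said not to have passed. It also took the 5 with the highest mean, per list the 2 members with the smallest p in the list's direction and 1 in the other, and up to 3 host genes per direction. A pair of circRNAs that it named is not reported here. CircRNAs named outside it are said to have been chosen after their values were seen. The alternatives were other pseudocounts, filters, scalings, a replicate block, library weights, thresholds, an exact rank-sum test and leaving out each library. Treating zeros as missing, a minimum of 10 read-pair equivalents, a fit without the variance trend, hosts by both exon ends only and an estimated correlation for circRNAs above 0 in all 12 libraries were added after the data were seen.

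The limma step was tested on simulated data for the 3870 circRNAs of the comparison of PZH with Control, 200 of them changed. With zeros from sampling alone, 64 of 67 4-fold changes below 20 read-pair equivalents were recovered and 33 of 33 at 20 or more. For 2-fold changes the numbers were 17 of 72 and 17 of 28. When calls were also dropped at the share seen in the table, 3 of 67 and 18 of 33 4-fold changes and 1 of 72 and 1 of 28 2-fold changes were recovered. That share already includes zeros from sampling, which were thus added again, and 3662 circRNAs were left to test. Calls were also dropped at random over circRNAs of a level and over libraries. These last numbers may therefore understate the recovery in the real data. In both simulations the means were taken from entries above 0. A single dispersion, 0.0759, from circRNAs above 0 in all 12 libraries, was used for every circRNA. The numbers with zeros from sampling alone may therefore overstate the recovery of low circRNAs. In that simulation mainly 2-fold changes below 20 read-pair equivalents were lost, and the further loss came with the dropped calls. How far depth limits the real data is not shown by it.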

Results

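Back-spliced RNA was compared between the livers of 6 mice given CCl4 and 6 mice given CCl4 and PZH, to ask which circRNAs differ when PZH is added during the toxin treatment. The table held 16445 circRNAs from 4727 host genes. Most were rare: 7262 were above 0 in a single library, 3870 in at least 6 libraries and 1089 in all 12, and these 1089 carried 66.5% of the summed signal. The libraries held 92559 to 129699 read-pair equivalents in PZH and 80442 to 130487 in Control. Among the 1089 circRNAs, log2 values correlated across circRNAs, which are not independent replicates, with r of 0.864 to 0.887 between PZH libraries, 0.840 to 0.878 between Control libraries and 0.826 to 0.876 between groups. No library looked like a copy of another. Of 1081 circRNAs above 0 in at least 6 libraries and with a median of at least 20 read-pair equivalents where above 0, 299 were listed at 0 in at least 1 library.

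**Figure D1:**
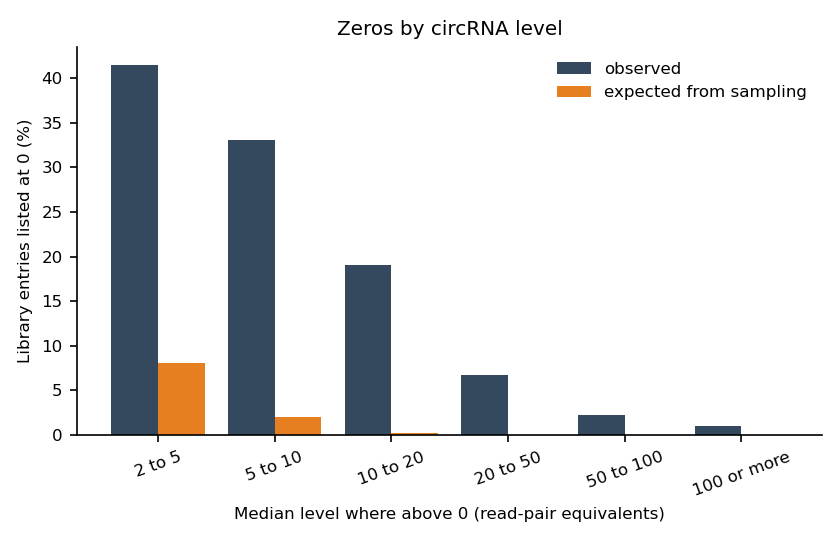
Share of library entries listed at 0 (y axis, %) for circRNAs above 0 in at least 6 libraries, by their median level where above 0 (x axis, read-pair equivalents); dark bars are observed shares and orange bars those expected from negative binomial sampling around the mean where above 0. At 20 to 50 read-pair equivalents 6.73% of entries were at 0, against an expected 0.00189%.

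The 5 most abundant liver circRNAs differed between the groups by less than 1 SD. The circRNA of exons 2 to 3 of Asph, which encodes aspartate beta-hydroxylase, averaged 741 ± 87.3 SRPBM in PZH and 772 ± 110.4 in Control (SD, n = 6 each). Those of Tlk1, a tousled-like kinase (614 ± 49.6 and 640 ± 81.8), Rnf169, a ubiquitin ligase of the DNA damage response (612 ± 50.7 and 590 ± 70.3), and Gigyf2 (332 ± 39.1 and 326 ± 36.9) followed. The circRNA of exons 5 to 6 of Adk, adenosine kinase, averaged 320 ± 89.6 SRPBM in PZH and 400 ± 111.9 in Control, with an adjusted p of 0.686 in limma. The log2 fold changes of the 5 were between -0.31 and 0.06, and that of Gigyf2 changed sign with median-of-ratios scaling and with scaling by summed SRPBM.

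With PZH, 2 circRNAs were higher and none was lower at an adjusted p under 0.05 in limma as set up before the data were examined, and lower calls appeared in other settings. The first came from Ttc39c, which encodes a tetratricopeptide repeat protein. Its circRNA of exons 2 to 6 was at 88.6 ± 21.1 SRPBM in Control and 164 ± 9.41 in PZH (SD, n = 6 each). On the log2(SRPBM + pseudocount) scale this was a 1.90-fold rise. All 6 PZH libraries (152 to 176) lay above all 6 Control libraries (51.5 to 106). The other came from Acbd5, which encodes an acyl-CoA binding protein of peroxisomes. Its circRNA of exons 7 to 10 was at 4.65, 11.5, 6.17, 2.20, 4.00 and 3.76 SRPBM in the 6 PZH libraries and listed at 0 in all 6 Control libraries. In limma the log2 fold change of the Ttc39c circRNA was 0.93 (SE 0.15, 95% interval 0.62 to 1.23) with an adjusted p of 0.00958, at a mean of 395 read-pair equivalents. The adjusted p of the Acbd5 circRNA was 0.0390. Of the 3870 circRNAs tested, 292 had an unadjusted p under 0.05, 176 higher and 116 lower with PZH, where 193.5 would be expected by chance. These were 174 and 151 with median-of-ratios scaling, 173 and 149 with scaling by summed SRPBM and 181 and 154 with quantile normalization. Without PZH replicate 2 they were 130 and 134, and without Control replicate 3 they were 209 and 79. The median log2 fold change was 0.06. Without the variance trend, a fit added after the data were seen, the adjusted p of the Ttc39c circRNA was 0.522 and those of the Acbd5 circRNA and of a Sos2 circRNA 0.000815 each. Leaving out any Control library moved the Acbd5 circRNA to an adjusted p between 0.0623 and 0.0923. Without any PZH library it was above 0 in too few libraries to be tested. The exact rank-sum test called no circRNA.

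**Figure D2:**
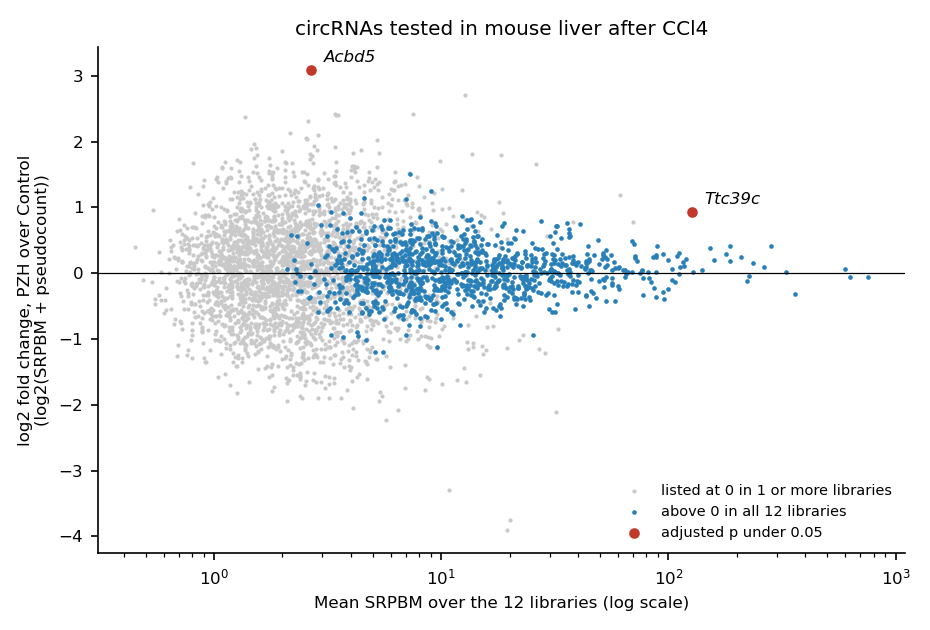
Log2 fold change of PZH over Control (y axis) against mean SRPBM (x axis, log scale) for the 3870 circRNAs tested; grey points were listed at 0 in at least 1 library, blue points were above 0 in all 12, red points had an adjusted p under 0.05 in limma. The Ttc39c point at 0.93 lies apart from other circRNAs of similar level, and Acbd5 is among the low circRNAs with zeros.

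The Ttc39c circRNA lies on chromosome 18 from 12684837 to 12698059 (GRCm38, plus strand). Its ends span the last part of the 5' UTR and the first part of the coding sequence, with 817 bp of annotated exon between them. Only the junction was measured, so which of these exons the circle holds is not known. A pair of further Ttc39c circRNAs was above 0 in all libraries. That of exons 2 to 4, which shares the start, averaged 34.7 ± 4.67 SRPBM in PZH and 32.9 ± 7.71 in Control, a log2 fold change of 0.11 (SE 0.19). That of exons 9 to 10 averaged 43.2 ± 12.8 and 29.6 ± 8.76, a log2 fold change of 0.54 (SE 0.21, adjusted p = 0.566 in limma). A circRNA of exons 2 to 5 with the same start was above 0 in 5 PZH and 2 Control libraries, with a log2 fold change of 1.19 (SE 0.67, adjusted p = 0.686). The log2 ratio of the exons 2 to 6 circRNA to the sum of those of exons 2 to 4 and 9 to 10 was higher by 0.61 in PZH (n = 6 each, exact permutation p = 0.00866, 2-sided). As the exons 2 to 6 circRNA was picked for its rise, this is not a separate test of the rise. Of its ratios to single circRNAs, which have the same limit, that to exons 2 to 4 was higher by 0.82 (exact permutation p = 0.00216). That to exons 9 to 10, chosen after the values were seen, was higher by 0.38 (exact permutation p = 0.197). The Acbd5 circRNA lies on chromosome 2 from 23087485 to 23094517, in coding exons of the plus strand. The circRNA of exons 8 to 9 inside it was at 32.6 ± 3.36 SRPBM in PZH and 33.1 ± 5.26 in Control, a log2 fold change of -0.02 (SE 0.16).

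**Figure D3:**
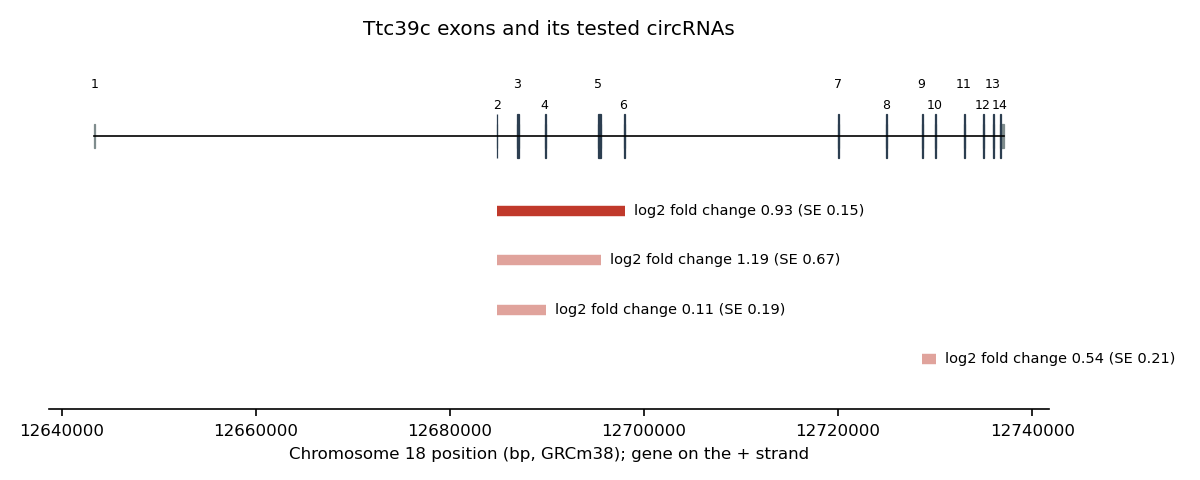
Exons of Ttc39c (numbered, coding parts taller) and its 4 tested circRNAs as bars by chromosome 18 position (x axis, bp, GRCm38), with log2 fold changes of PZH over Control and standard errors from limma. The exons 2 to 6 circRNA, in dark red, is the one past the threshold, at 0.93. Of those with the same start, the exons 2 to 4 circRNA is at 0.11 and the exons 2 to 5 circRNA at 1.19.

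Next to these, 8 circRNAs with higher and 10 with lower levels in PZH had the smallest p without passing, at adjusted p of 0.102 to 0.454 in limma. On the higher side were circRNAs of Rreb1, a zinc finger transcription factor of RAS signalling (40.1 ± 6.01 SRPBM in PZH, 24.3 ± 4.32 in Control), Dtnb, beta-dystrobrevin (50.8 ± 5.91 and 30.9 ± 8.92), Fmo5, a flavin monooxygenase of liver (34.6 ± 5.37 and 20.1 ± 5.51). They also included Aass, which starts lysine breakdown (45.7 ± 16.1 and 25.9 ± 4.32), and the noncoding gene Gm40438 (10.8 ± 2.42 and 3.75 ± 2.39). Circles of Sos2 and Lsm14a were above 0 in all 6 PZH libraries, at 1.91 to 3.93 and 0.704 to 4.00 SRPBM, and listed at 0 in all 6 Control libraries. That of Smyd4 was at 4.85 to 7.21 SRPBM in PZH and listed at 0 in 3 of 6 Control libraries. Those on the lower side included circRNAs of Ddx17, an RNA helicase (24.6 ± 4.25 SRPBM in PZH, 36.7 ± 1.90 in Control), Pzp, a plasma protease inhibitor (6.13 ± 2.69 and 13.1 ± 2.17). So were those of Crebbp, a histone acetyltransferase (24.1 ± 3.93 and 35.5 ± 5.92), and Paip2 (3.12 ± 1.01 and 7.97 ± 2.28). Vps13b and Mtmr3 were listed at 0 in 1 and 5 of 6 PZH libraries. CircRNAs of Lemd3, an inner nuclear membrane protein that binds SMADs, and Pcdh17, a protocadherin, were above 0 in all 6 Control libraries, at up to 42.5 and 23.8 SRPBM. Both were listed at 0 in 4 of 6 PZH libraries, with 19.0 and 39.6 and with 16.2 and 10.6 SRPBM in the remaining ones. Each passed as lower in 5 of 24 settings. That of Nedd4l, a ubiquitin ligase, was at 23.0 to 52.6 SRPBM in 5 Control libraries and 40.2 in 1 PZH library, and listed at 0 in the others.

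**Figure D4:**
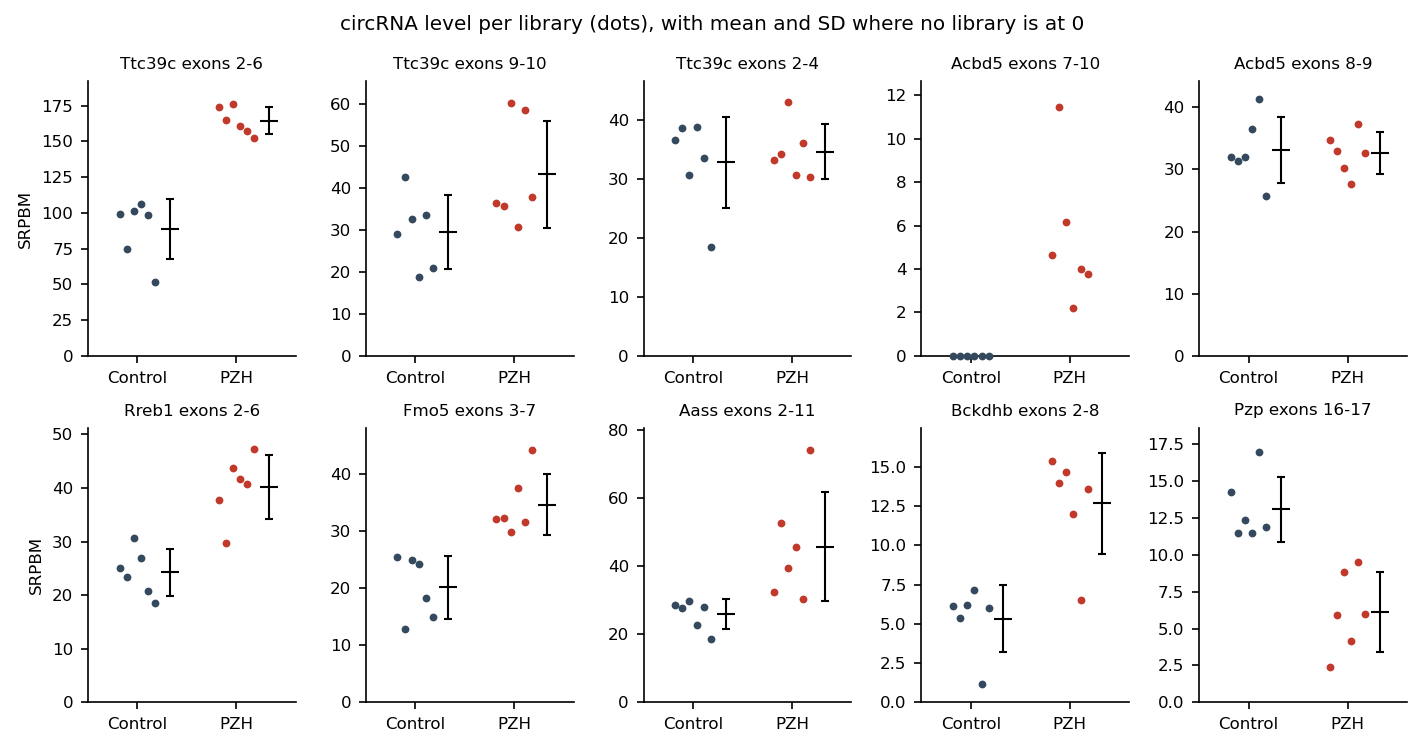
SRPBM (y axis) of 10 circRNAs in each Control (dark) and PZH (red) library; each dot is 1 mouse, and the black mark is the mean with SD where no library is at 0. The Ttc39c exons 2 to 6 circRNA spans 152 to 176 in PZH and 51.5 to 106 in Control, and the Acbd5 exons 7 to 10 circRNA is at 0 in every Control library.

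None of the 16 host gene lists differed from the other circRNAs (camera, smallest adjusted p = 0.501, and 0.928 or more with an estimated correlation). Over all circRNAs tested, no list member passed the threshold. Adjustment over a list alone, given here and below, was not corrected for the testing of 16 lists. Among the lists for scar tissue, 9 of 12 circRNAs of extracellular matrix genes and 7 of 8 of hepatic stellate cell markers had positive log2 fold changes (camera adjusted p = 0.579 for both). Adjusted over the list alone, 1 stellate circRNA was higher, that of Dlc1, at 0.976 to 8.36 SRPBM in all 6 PZH libraries and listed at 0 in 5 of 6 Control libraries. A Reln circRNA, from a stellate marker gene, was above 0 in 5 PZH and 3 Control libraries, while one of Zeb2 was above 0 in 3 PZH and 5 Control libraries. Of matrix genes, that of the integrin Itga9 was above 0 in 6 PZH and 2 Control libraries, that of Itga8 in 5 and 2, and that of the laminin chain Lamc1 in 5 and 6. For TGF-beta and SMAD signalling, 16 of 37 were positive and 21 negative (adjusted p = 0.579), with 1 lower when adjusted over the list alone, the Nedd4l circRNA above. A second Crebbp circRNA of that list, of exons 3 to 5, was higher in PZH at 9.44 ± 3.95 SRPBM against 5.31 ± 2.94 but did not pass (limma adjusted p = 0.686).

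Markers of other liver cells gave no call over all circRNAs tested. Of macrophage and immune circRNAs, 13 of 22 were positive (camera adjusted p = 0.777). Of Adgre1, which encodes the macrophage antigen F4/80, 2 circRNAs had an unadjusted p under 0.05. That of exons 11 to 12 averaged 28.9 ± 6.59 SRPBM in PZH and 21.2 ± 5.78 in Control, and that of exons 6 to 12 was above 0 in 6 PZH and 2 Control libraries. A circRNA of Plcg2 in that list was listed at 0 in 4 PZH libraries. For endothelial markers, 13 of 19 were negative (adjusted p = 0.579), among them Plxnd1, above 0 in 2 PZH and 5 Control libraries, and Dock4, in 1 and 5, while that of Mef2a averaged 23.1 ± 1.97 and 17.3 ± 5.02. For cholangiocyte and progenitor markers, 7 of 11 were positive (adjusted p = 0.579). Adjusted over the list alone, 1 was higher, the circRNA of exons 3 to 6 of Fgfr2, a fibroblast growth factor receptor, at 26.3 ± 3.78 SRPBM in PZH and 16.6 ± 3.35 in Control. The Fgfr2 circRNA of exons 4 to 6 averaged 14.3 ± 3.22 and 8.62 ± 2.19, and that of exons 3 to 4 averaged 14.1 ± 3.31 and 15.8 ± 3.55.

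Lists of hepatocyte functions gave no call over all circRNAs tested. For fatty acid, triglyceride and cholesterol metabolism, 32 of 52 circRNAs were negative, the median log2 fold change was -0.15, and the list had the smallest p of all (camera adjusted p = 0.501, and 0.928 with an estimated correlation). Its members included one of the acyl-CoA synthetase gene Acsm1, above 0 in 2 PZH and 6 Control libraries. On the other side was one of Mlxipl, which encodes the glucose-responsive factor ChREBP, at 171 ± 12.2 SRPBM in PZH and 133 ± 23.7 in Control (limma adjusted p = 0.430). For amino acid and urea cycle metabolism, 31 of 47 were positive (camera adjusted p = 0.579), and 5 had an unadjusted p under 0.05 on the higher side. They included the Aass circRNA and 3 of Bckdhb, a subunit of the branched-chain keto acid dehydrogenase, of which that of exons 2 to 8 averaged 12.7 ± 3.22 SRPBM in PZH and 5.34 ± 2.12 in Control. A circRNA of Cps1, the first enzyme of the urea cycle, was above 0 in 4 PZH and 6 Control libraries. Among the 10 circRNAs of this list above 0 in all 12 libraries, camera with its preset correlation gave an adjusted p of 0.0362 on the higher side, against 0.0362 to 0.965 over its settings. With the correlation estimated for these 10, of which 3 are Bckdhb circRNAs, it was 0.870, and for all 47 it was 0.937.

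Drug metabolism had 24 of 39 positive circRNAs (camera adjusted p = 0.777), with 1 higher when adjusted over the list alone, that of Fmo5, next to one of Dpyd above 0 in 6 PZH and 3 Control libraries and one of Cyp2j5 in 2 and 5. Bile acid synthesis and transport had 24 of 38 (adjusted p = 0.777). The circRNA of the canalicular pump Abcc2 averaged 96.1 ± 12.8 SRPBM in PZH and 79.5 ± 10.2 in Control, and that of Scp2, sterol carrier protein, 45.7 ± 9.02 and 61.1 ± 11.1. That of the uptake transporter Slco1b2 was listed at 0 in 1 Control library. Plasma proteins, complement and coagulation had 27 of 47 negative (adjusted p = 0.579), including 2 of Pzp, the second above 0 in 1 PZH and 5 Control libraries, while one of the growth hormone receptor gene Ghr was above 0 in 6 and 5.

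**Figure D5:**
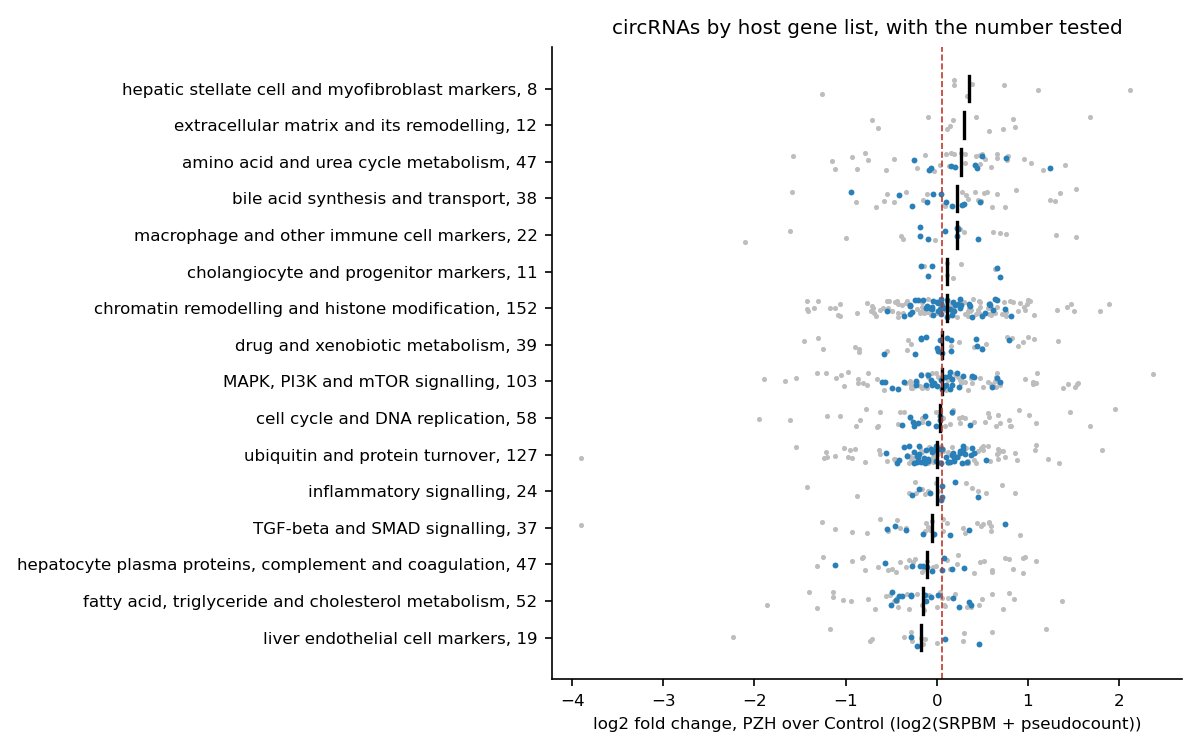
Log2 fold changes of PZH over Control (x axis) of the tested circRNAs of the 16 host gene lists (y axis, with the number tested); blue points were above 0 in all 12 libraries and grey points were not, black bars are list medians and the dashed line is the median of all circRNAs, 0.06. Every list holds circRNAs on both sides of 0, and no list passed camera.

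Signalling and housekeeping lists were centred near the median of all circRNAs. MAPK, PI3K and mTOR signalling had 55 of 103 positive (camera adjusted p = 0.930), with 1 higher when adjusted over the list alone, that of the RAS exchange factor Sos2. One of Map4k5 was at 36.9 ± 6.47 SRPBM in PZH and 52.6 ± 12.1 in Control. This was also the list for which fry, run without the variance trend, found change in either direction, which is not a comparison with other genes (mixed adjusted p = 2.76e-05). In limma without the trend, the Sos2 circRNA of this list, listed at 0 in all 6 Control libraries, had an adjusted p of 0.000815. Whether the fry result rests on that member was not tested. On host gene sums the mixed adjusted p of this list was 0.131 in fry. Those of hepatic stellate cell markers and of bile acid synthesis and transport were 0.0249 each. Chromatin genes had 89 of 152 positive (camera adjusted p = 0.636). They included the circRNA of exons 2 to 3 of Ezh2, a histone methyltransferase, at 40.0 ± 7.33 and 27.2 ± 2.68, and one of Setd2, above 0 in 5 PZH and 1 Control libraries. Ubiquitin and protein turnover had 64 of 127 positive (adjusted p = 0.777), with one of Ulk2 above 0 in 6 PZH and 2 Control libraries. Cell cycle had 31 of 58 positive (adjusted p = 0.889), and its median (0.03) and mean (0.05) were above 0 though below other circRNAs. Its circRNAs of Ccny and Mdm2 were above 0 in 2 and 4 PZH and in 6 Control libraries, and that of Cdk14 in 6 PZH libraries and 1 Control library. Inflammatory signalling had 12 of 24 (adjusted p = 0.930), with one of Tbk1 above 0 in 2 PZH and 6 Control libraries, one of Rel in 2 and 4, and one of Pias2 at 10.7 ± 2.16 and 8.03 ± 3.05.

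Summed over host genes, no gene passed in limma. Of 2204 host genes tested, 181 had an unadjusted p under 0.05, 112 higher and 69 lower, where 110.2 would be expected by chance. The sum of Ttc39c was the closest, at 247 ± 23.7 SRPBM in PZH and 153 ± 30.6 in Control, a log2 fold change of 0.72 (SE 0.14, adjusted p = 0.0683). The sum of Rreb1 was 50.3 ± 8.56 and 29.6 ± 8.38 (adjusted p = 0.229). That of Reln, a stellate cell marker, was 4.12 to 11.7 SRPBM in the 6 PZH libraries and at most 3.32 in Control (adjusted p = 0.205). On the lower side stood Lemd3, Pcdh17 and Nedd4l, at adjusted p of 0.205 to 0.264.

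The liver's circRNA output as a whole differed between the groups by less than the spread between mice. Summed circRNA was 36240 ± 3936 SRPBM in PZH and 35196 ± 4751 in Control (SD, n = 6 each, exact permutation p = 0.680, 2-sided). Per library, 5060 ± 390 and 4859 ± 660 circRNAs were above 0 (exact permutation p = 0.556). By presence alone, 45 circRNAs were above 0 in at least 5 PZH and at most 1 Control library, and 25 the other way round. By a rule of at least 4 libraries against none the numbers were 44 and 35. Among them those of Acbd5, Sos2 and Lsm14a were above 0 in every PZH library and no Control library, and none showed the opposite. The profiles of the groups were slightly apart: the mean distance of log2 profiles was 96.9 between groups and 95.7 within, a difference of 1.26 (exact permutation p = 0.0173, 1-sided). With a Spearman distance and with median-of-ratios scaling the exact permutation p was 0.00216 each, and among circRNAs above 0 in all 12 libraries 0.00433. Without any 1 of the 6 PZH libraries the p of the main setting was 0.0563 to 0.0952.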

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

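The gap between the farthest library and its nearest neighbour, over the whole range of a group's 6 libraries, set apart 15 of 128 groups of values. For normally distributed values chance sets apart about 1 in 20 groups, which does not hold for groups with zeros, since 1 value above 0 among 5 zeros always gives a ratio of 1. Of 45 groups with zeros 11 were set apart, and of 83 without zeros 4, where about 4.15 would be by chance. These were single libraries far from the others of their group, and no explanation was tested for them.

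In 7 groups this ratio was 1, because 1 library was above 0 and the other 5 were listed at 0. They were PZH replicate 5 for Nedd4l (40.2 SRPBM), replicate 4 for Mtmr3 (0.621), replicate 2 for Dock4 (1.25) and replicate 1 for the Pzp circRNA of exons 7 to 11 (0.680). In Control they were replicate 4 for Dlc1 (2.81) and Setd2 (0.996) and replicate 6 for Cdk14 (1.41). In 4 further groups with zeros the highest library stood apart: Control replicate 3 for Itga9 at 7.20 SRPBM (ratio 0.904), PZH replicate 6 for Ccny at 3.66 (0.748), Control replicate 4 for the Reln circRNA at 3.32 (0.716), and PZH replicate 4 for Acsm1 at 4.69 (0.659).

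Among values above 0 in every library of the group, PZH replicate 1 was highest for Ghr at 6.13 SRPBM, with the others at 2.75 to 3.50 (ratio 0.779). PZH replicate 3 was highest for the Adgre1 circRNA of exons 11 to 12 at 41.8, with the others at 23.1 to 28.4 (0.716). PZH replicate 5 was lowest for Abcc2 at 71.6, with the others at 96.5 to 108.6 (0.673). Control replicate 5 was lowest for the Bckdhb circRNA of exons 2 to 8 at 1.17, with the others at 5.40 to 7.15 (0.707).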

How the results depend on the processing

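The alternatives with zeros as missing, a minimum level, no variance trend, hosts by both exon ends and an estimated correlation above 0 in all 12 libraries were chosen after seeing the data, and the cause was not tested where none is given. Against 2 called circRNAs, 4 were called with 4 times the pseudocount (2 of them lower), 30 without a filter (11 lower), 6 with a filter of at least 3 libraries (3 lower) and 10 among circRNAs above 0 in all 12 libraries (2 lower). There were 209 at an unadjusted p under 0.05 with a 2-fold change. The exact rank-sum test called 0 and had 266 at an unadjusted p under 0.05. Its smallest possible p, 0.00216, was reached by 26 circRNAs against 8.38 expected, too few to pass the adjustment. With zeros as missing 15 were called (6 lower), and 1 with a mean of at least 10 read-pair equivalents. Without the variance trend there were 2 calls (Acbd5 and Sos2, 1 shared with the calls above), 0 above 0 in all 12 libraries, and 0 with zeros as missing, so the calls among circRNAs above 0 in all 12 libraries depend on the trend. The unfiltered fit gave the Ttc39c circRNA an adjusted p of 9.9e-32, which is not read as strength of evidence since most circRNAs in that fit were at 0 in nearly every library. Over 28 settings the Ttc39c circRNA stayed higher in PZH (log2 fold change 0.78 to 0.99) and passed in 25, and Acbd5 passed in 10 of 17.

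Against 0 called host genes, 1 was called with 4 times the pseudocount, 6 without a filter, 2 with at least 3 libraries, 1 with all 12, 1 with median-of-ratios scaling, 1 with scaling by summed SRPBM, 1 at an adjusted p under 0.1, and 100 at an unadjusted p under 0.05 with a 2-fold change. Against 0 host gene lists, 1 was called among circRNAs above 0 in all 12 libraries, and 0 there with the estimated correlation. Presence in all 6 against none gave 3 circRNAs instead of 70, by the stricter rule. The log2 fold change of Gigyf2 reversed to -0.015 with median-of-ratios scaling and -0.021 with summed SRPBM.

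Leaving out each library in turn gave 1 to 3 circRNAs (3 without PZH replicate 5, of which 2 were lower, 2 without PZH replicate 1 or 3 or Control replicate 1, of which 1 was lower, and 1 without PZH replicate 2, 4 or 6 or Control replicate 2, 3, 4, 5 or 6). It gave 0 to 3 host genes (3 without PZH replicate 5, 1 without PZH replicate 3 or Control replicate 6), 0 lists, and 129 to 149 circRNAs present in one group, by a looser rule of at least 4 of the 5 left. The difference in summed circRNA was -211 to 2190 SRPBM and in circRNAs detected -23.8 to 329, both reversed without Control replicate 2. The separation was 0.793 to 1.72, past its threshold in each case without a Control library and in none without a PZH library. Gigyf2 ranged from -0.015 to 0.086, below 0 without PZH replicate 2 or Control replicate 1 or 2, and Asph from -0.12 to 0.0020, above 0 without Control replicate 3. With the replicate block there was 1 called circRNA (Ttc39c) and 2 host genes. Same-numbered libraries did not deviate together (correlations -0.046 to 0.016, own number best in 0 of 6). No sign of pairing by number was thus seen, which cannot show that the mice were unpaired. Count models and thinning of reads were not run, since whole reads could not be recovered. Of the values of single circRNAs and hosts, taken with the counts of higher and of lower circRNAs, 1628 were kept, in direction and side of the threshold. Another 50 passed it only in the other setting, among them Adk, Asph and Mlxipl without a filter. A further 10 no longer passed, 6 reversed and 28 counts moved. Of the main results, 92 were kept, 45 counts moved, 6 no longer passed and 2 reversed. A count within 1.5 times was taken as kept (3 against 2, for example).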

Other observations

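The fits with zeros as missing or without the variance trend, the splits used for called circRNAs, unadjusted p, host genes, lists and presence, the comparisons of zeros with sampling and with the implied mapped reads, and the scaling and zero tests and the ratio to exons 9 to 10 of the Ttc39c circRNA were chosen after their results were seen.

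The host genes with the most circRNAs in the table gave 30 or more each. Dpyd, which encodes the enzyme that breaks down pyrimidines, gave 48 different circRNAs, Mllt10 gave 38, Gphn and Vwa8 36 each, and Rere and Ehmt1 35 each. Asph gave 30, with a summed mean of 934 SRPBM against 66.3 for Dpyd. Among circRNAs above 0 in at least 6 libraries the median length of annotated exon between the ends was 389 bp. Of those with exon numbers 28.0% began at exon 2, as did those of Ttc39c, Rreb1 and Aass.

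Among the 1089 circRNAs above 0 in all 12 libraries, limma called 10, of which 8 were higher with PZH (Ttc39c, Rreb1, Dtnb, Fmo5, Aass, Bckdhb, Gm40438 and Pms1) and 2 were lower (Pzp and Mob3b). The Pms1 and Mob3b circRNAs, chosen after their values were seen, had log2 fold changes of 0.72 and -0.94. Without the variance trend 0 were called. All 10 were also among the 15 called with zeros as missing, which is not a second test, since these 10 have no zeros and enter both fits with the same values. The 3 circRNAs of Bckdhb above 0 in all libraries had log2 fold changes of 1.24, 0.49 and 0.41.

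Other splits of the 12 libraries into 6 and 6 show which counts chance can give, from 100 splits. As many called circRNAs as the real 2 came from 3 splits, the real one included, with 2 as the highest other. As many as 292 at an unadjusted p under 0.05 came from 1, with 274 as the highest other. As many as the 181 host genes at an unadjusted p under 0.05 came from 4, with 188 as the highest other. The share of splits was thus under 0.05 for each count, but only 100 splits were drawn, after the results were seen. Other splits equalled the 2 calls and passed the 181 host genes, so chance was not excluded for either count. No other split drawn gave as many as 292, which argues against chance for that count. It does not carry over to either called circRNA, since 8 other splits gave at least 1 call. As many as the 10 calls above 0 in all 12 libraries came from 2 splits. The highest other was 12, in a split that exchanged 1 mouse of each group, so chance was not excluded there. As many as the 15 with zeros as missing came from 1 split (highest other 11). Of these 15, 10 are the calls above 0 in all 12 libraries, and without the variance trend 0 were called. With the trend, that fit hardly used the spread of each single circRNA (26447 degrees of freedom). Chance was thus not excluded for the 15 either. For the 70 circRNAs present in one group chance was not excluded (18 splits, highest other 83). For 0 host genes and 0 lists any split gives as many (100 splits each, highest other 1), so the splits decide nothing there.

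Abundant circRNAs were often listed at 0: among 1081 circRNAs above 0 in at least 6 libraries and with a median of at least 20 read-pair equivalents where above 0, 626 of 12972 entries were at 0. Sampling of few read pairs argues for far fewer, since 2.37 would be expected at each circRNA's own dispersion (a ratio of 264) and 49.1 at 5 times the shared one. Means and own dispersions were taken from entries above 0, which lowers the numbers expected. A junction called at shifted coordinates was found within 20 bp for 0.160% of the entries, which argues against shifts of that size. Of the 299 circRNAs with such zeros, 14 had any junction that near. The mean number of zeros per library differed by -2 between PZH (51.2 ± 13.6) and Control (53.2 ± 23.1, n = 6 each, exact permutation p = 0.881). Zeros of single circRNAs that went with treatment in opposite directions would cancel in this number, so it cannot exclude a treatment effect on them. The number fell with the summed read-pair equivalents (Spearman rho -0.900, permutation p = 0.00026; Pearson r -0.880, permutation p = 0.0002; r -0.909 without the 2 libraries farthest from the median), also when these were summed over circRNAs above 0 in all 12 libraries (rho -0.900; r -0.846, permutation p = 0.0012), which is circRNA yield and not sequencing depth. With the mapped reads implied by each library's smallest value the relation was weaker (rho -0.504, permutation p = 0.0983; r -0.658, permutation p = 0.0210), so library depth stays open as a cause, and the caller is not given in the sources used here.

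The higher Ttc39c circRNA of exons 2 to 6 was weighed against scaling, missing calls and a change of the whole gene. Its log2 fold change was 0.78 or more under 3 other scalings and it was listed at 0 in 0 libraries, which argues against the first and second. Its log2 ratio to the sum of the other Ttc39c circRNAs above 0 in all libraries was higher in PZH (exact permutation p = 0.00866). As it was picked for its rise, which by itself raises this ratio, the ratio cannot decide against an equal change of all of them. Linear Ttc39c RNA was not measured in the values used here. A change shared with some or all thus stays open. The ratio to the exons 9 to 10 circRNA alone was not separated (exact permutation p = 0.197). The exons 2 to 5 circRNA, listed at 0 in 5 libraries, had a log2 fold change of 1.19. A PZH effect on this circRNA, or on several of the gene, may be the source, as a hypothesis found and tested on the same data, and the call itself stays open, since without the variance trend its log2 fold change was also 0.93 but its adjusted p 0.522 (0.0909 among circRNAs above 0 in all 12 libraries, 0.266 with zeros as missing), against 0.00236 to 0.0488 with the trend and without single libraries.

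The Acbd5 circRNA, listed at 0 in all 6 Control libraries, was 1 of 3 circRNAs above 0 in every library of one group and none of the other. As many or more came from 11 of 100 splits, with 6 as the highest other, so missing calls unrelated to treatment could have produced it. Its level in PZH was 7.08 to 37.6 read-pair equivalents. For circRNAs above 0 in at least 6 libraries with a median of 10 to 20 where above 0, 19.0% of entries were at 0. The other Acbd5 circRNAs did not go with it: that of exons 8 to 9 had a log2 fold change of -0.02 and that of exons 10 to 11, listed at 0 in 2 PZH libraries, one of -1.27 (limma adjusted p = 0.654). A PZH effect was not tested apart from missing calls.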
